A study of Homo sapiens with 13 samples.

How the data were processed

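TrAEL-seq captures free 3' ends of genomic DNA by adding a short tail and ligating an adaptor to it, so that each read marks one DNA end and the strand it lay on. Most such ends in dividing cells come from replication forks, and the balance of reads between the strands of a window then follows the direction in which forks cross it. It was applied to PC9, an established human lung adenocarcinoma cell line with an activating EGFR mutation. Osimertinib is an EGFR inhibitor; it was given at 500 nM, per the labels' protocols. The 13 libraries comprised 3 untreated libraries, 2 after 7 days, 2 after 14 days and 4 after 28 days of osimertinib, and 2 from resistant lines that had each been derived from a single-cell clone and kept in the drug. The resistant lines carry the names 5 and 10 and had 1 library each. Per the series' design text, the 28-day cultures did not proliferate, whereas the untreated cells and the resistant lines were growing when taken.

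The labels of 2 libraries conflicted: replicates 3 and 4 titled day 28 had a treatment label of 7 days. They were kept at day 28 by their titles, and the comparisons of amplitude, zones, windows and genes were repeated without them and, for the first 3 of these, with them placed at day 7. The measures of reach, the mitochondrial and ribosomal tests, the comparison of lists with random lists and the correlation of changes were not repeated in this way. Nothing in the labels states that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

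The deposited values are strand polarities in percent, from -100 to 100, as read from the values: the difference of the reads on the 2 strands divided by their sum, for windows of 20 kb every 10 kb. Polarity is a ratio within a library and needs no scaling for library size. Reads were processed with Trim Galore 0.6.5 and Bowtie2 2.4.1, and the builds GRCh38 and GRCm38 are named, per the submitters' processing notes; the chromosome ends in the deposited table equal those of GRCh38. Which strand counts as positive, the read counts and the minimum number of reads behind a value are not given in the sources used here. The depth of each library is therefore unknown, no counting intervals were given, and the share of windows with a value was used only as a guide to it. Planned tests of read density, of the share of reads per chromosome and of counts thinned to equal depth were not run, because they need counts. Rises of polarity along the untreated genome were steeper than falls (over 60 kb, the 99.5th percentile of the change was 99.0 points and the 0.5th was -66.0). Rises were therefore treated as initiation zones, where forks leave in both directions, and positive polarity as rightward forks. That assignment was made after the data were seen; turning the sign would exchange initiation and termination zones and leave amplitudes as they are.

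Of the 308844 windows, the 151538 non-overlapping full windows of chromosomes 1 to 22 and X were used. The amplitude of a library was the slope of its polarity on the mean profile of pairs of untreated libraries that left the library itself out, over the 80351 windows (53.0%) with a value in all 13 libraries. Such a slope is not raised by counting noise in the tested library, whereas noise in the reference profile lowers all slopes alike. Initiation zones were unbroken rises of the smoothed mean of untreated pairs (4 windows, 80 kb) from below to above 0 by at least 40 points, and termination zones were the mirror image. The rise across each zone (mean of 3 windows at its right end minus 3 at its left end) was measured in libraries not used to call it. Groups of libraries were compared by two-sided exact permutation of the library values, and correlations by 100000 permutations for 11 libraries and by exact permutation for 8 or fewer. On simulated profiles scaled by 0.3 the zone rise recovered a ratio of 0.302 and the slope one of 0.300.

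Single windows were tested with limma 3.58.1 (lmFit and eBayes with a trend) on the polarity values, with all 13 libraries in 1 fit and Benjamini-Hochberg adjustment at 0.05. A simulation of day 28 against untreated at 20 kb recovered 0 of 100 windows changed by 30 points and 0 of 100 changed by 60 points without weights, and with array weights (limma's estimate of each library's precision) 2 and 60 of 100, with 5 false calls. At 100 kb it recovered 15 of 100 at 30 points and 99 of 100 at 60 points, with 0 false calls. With array weights the 100 kb fit recovered 67 and 100 of 100, with 4 false calls. Each simulation changed 200 windows, all with untreated polarity within 60 points of 0, and had no loss of amplitude. It therefore does not give the power for the genome-wide changes in the real data. Without weights, 1.56% of unchanged windows at 20 kb and 1.41% at 100 kb had an unadjusted p under 0.05 in limma. Genes were placed with the GRCh38.p14 RefSeq table. Gene polarity was the mean over the windows overlapping the gene (17061 genes tested). The rise across a gene was the mean of the 3 windows after it minus the mean of the 3 before it (12809 genes tested), where positive values mean that forks diverge from the gene's position. Neighbouring genes can share windows. The table gives no exons, so a window is described only as inside or outside a gene's span. A change is described as toward 0 where it ran against the sign of the untreated mean; since that same mean also picks windows with large untreated values, some excess of such changes is built into any list of called windows.

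The lists of genes, the comparisons, and those tests and alternatives not named as later choices here or in the closing section were fixed before the data were examined. Named regions are the 4 with the largest rise and the 4 with the largest fall of polarity among called windows changed in the same direction in every library, each given the protein-coding gene that overlaps it most or lies nearest. Called members of the lists are named too, and in each comparison EGFR, MET, ERBB2, MYC, CDKN2A, FHIT and WWOX; not every gene that the rule takes in is printed. Chosen after the data were seen were the requirement of a value in all 13 libraries, the rise across genes, the measures of reach (the covariance of polarity by distance and the ratio of slopes at 2 window sizes), the fits on values scaled to the untreated amplitude, and the comparison of lists with random lists. The tests of the mitochondrial genome and the ribosomal repeat were chosen later as well. The ratio of slopes used a slope corrected for noise in the reference profile (the covariance with 1 untreated library divided by the covariance of 2 untreated libraries). Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and in R 4.3.3; plots were drawn with matplotlib 3.10.9.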

Results

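Replication fork direction was profiled in 13 TrAEL-seq libraries of PC9 lung adenocarcinoma cells, before and during treatment with the EGFR inhibitor osimertinib and in 2 osimertinib-resistant lines. The design asks how replication differs between proliferating cells, cells that persist under the drug, and cells that grow in its presence. Untreated libraries had a polarity value in 92.6%, 92.6% and 93.4% of the 20 kb windows. The day 7 libraries had one in 61.4% and 92.0% and the day 14 libraries in 85.6% and 81.8%. The day 28 libraries (replicates 1 to 4) had one in 86.4%, 92.6%, 93.4% and 86.3%, and lines 5 and 10 in 93.0% and 93.1%. Read counts were not given, so the depth behind each value is unknown. The untreated libraries correlated with one another at Pearson r of 0.869 to 0.890 across windows, which are not independent replicates. The day 7 libraries correlated at 0.357, the day 14 libraries at 0.391, the day 28 libraries at 0.212 to 0.489 and the resistant lines at 0.658. With the untreated libraries, day 28 replicate 3, 1 of the 2 with conflicting labels, correlated at 0.765 to 0.829, and day 28 replicates 1, 2 and 4 at 0.339 to 0.346, 0.491 to 0.501 and 0.461 to 0.485. No library repeated the values of another.

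The alternation of leftward and rightward forks along the genome was clear in untreated cells and much flatter after osimertinib. In untreated libraries polarity rose by 87.7 ± 8.73 points (SD, n = 3) across initiation zones called from pairs of the other untreated libraries, with 3541 to 3743 zones per pair. Zones called from all 3 untreated libraries had a median width of 140 kb. Across the 8 osimertinib libraries of the parental line the rise was 31.4 ± 12.1 points (SD, n = 8), or 35.9% of the untreated rise. At day 7 it was 35.7 ± 13.7 points (SD, n = 2), at day 14 39.5 ± 17.2 points (SD, n = 2) and at day 28 25.2 ± 8.64 points (SD, n = 4). The fall across termination zones, where converging forks meet, went from 75.1 ± 10.5 points (SD, n = 3) in untreated libraries to 25.5 ± 10.3 points (SD, n = 8) under osimertinib. The polarity amplitude, the slope on the untreated profile over the windows with a value in all 13 libraries, was 0.937 ± 0.116 (SD, n = 3) untreated and 0.405 ± 0.141 (SD, n = 8) under osimertinib. The highest osimertinib value, 0.668 in day 14 replicate 2, lay below the lowest untreated value, 0.807. Both measures differed between osimertinib and untreated libraries with p = 0.0121 in two-sided exact permutation tests, the smallest p that 3 against 8 libraries allow; adjusted over the 6 comparisons it was 0.0727.

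**Figure D1:**
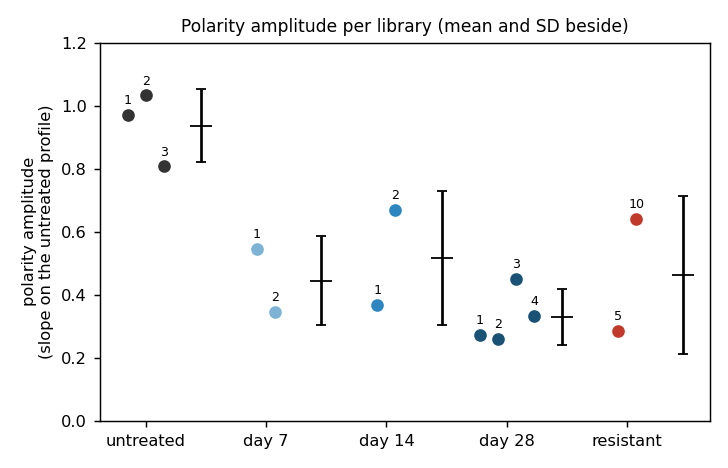
Polarity amplitude of each library, as the slope of its polarity on the untreated profile, by group; numbers beside the points are replicate numbers or line names, and the bars give the mean and SD of each group. The 3 untreated libraries lie between 0.807 and 1.03, and all other libraries lie between 0.261 and 0.668.

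**Figure D2:**
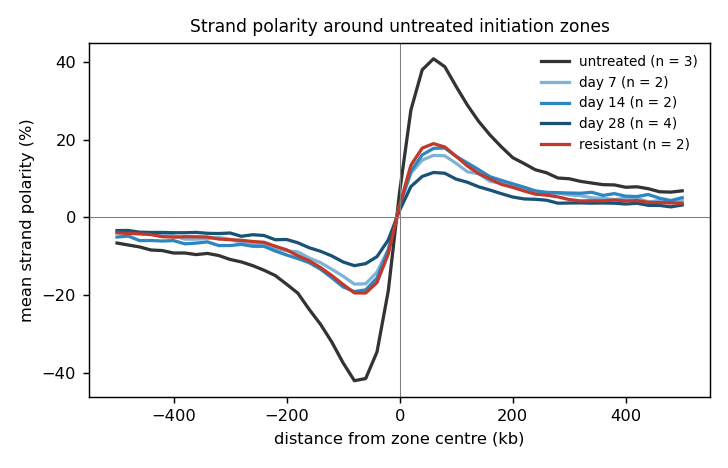
Mean strand polarity in percent against the distance in kb from the centre of untreated initiation zones, as the mean of the libraries of each group. The untreated curve reaches 40.8% at 60 kb to the right of the centre, the resistant curve 18.9% and the day 28 curve 11.5%.

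Among the treated libraries the mean amplitude was lowest at day 28, but the relation of amplitude to the day of treatment did not pass the test. The group means were 0.445 ± 0.141 (SD, n = 2) at day 7, 0.518 ± 0.213 (SD, n = 2) at day 14 and 0.329 ± 0.0877 (SD, n = 4) at day 28. Untreated and osimertinib libraries formed separate clusters, so the relation is given only within the treated ones. Within the 8 osimertinib libraries Pearson r was -0.50 (exact permutation p = 0.219, adjusted 0.267) and Spearman rho was -0.57 (exact permutation p = 0.157, adjusted 0.267; 6 correlations in the family). Without the day 7 libraries, which lay farthest from the median day, r within the treated libraries was -0.64. Without day 28 replicates 3 and 4, r over the remaining 6 was -0.58 and rho -0.60 (exact permutation p = 0.222 and 0.267, each adjusted to 0.267), and r turned to 0.28 when the 2 farthest, day 28 replicates 1 and 2, were left out too. The 2 libraries with conflicting labels, day 28 replicates 3 and 4, had amplitudes of 0.452 and 0.333, against 0.272 and 0.261 in day 28 replicates 1 and 2 and 0.545 and 0.345 at day 7.

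After 28 days of osimertinib, polarity was closer to 0 at genes across the genome, among them oncogenes that drive or bypass EGFR signalling. The genes named here were taken from the fixed lists and are examples of this genome-wide change. The oncogene MYC (chromosome 8, 127735434 to 127742951, GRCh38) lay to the left of a strong initiation zone. Its mean polarity went from -62.7% ± 4.3 (SD, n = 3) in untreated libraries to -13.2% ± 31.5 (SD, n = 4) at day 28 (limma adjusted p = 0.0222). The rise across it went from 107.6 ± 5.9 to 53.2 ± 16.7 points (adjusted p = 0.0465). At AXL (chromosome 19, 41219223 to 41261766), a receptor tyrosine kinase, the rise across the gene fell from 121.8 ± 15.9 to 25.1 ± 16.7 points (adjusted p = 0.00216). At ERBB2 (chromosome 17, 39688094 to 39728658), the receptor that pairs with EGFR, it fell from 52.9 ± 9.0 to 2.0 ± 17.4 points (adjusted p = 0.0128). At CCNE1 (chromosome 19, 29811991 to 29824312), the cyclin of S-phase entry, it fell from 103.4 ± 12.1 to 32.0 ± 15.6 points (adjusted p = 0.00362). EGFR itself (chromosome 7, 55019017 to 55211628) did not pass the test: its polarity was 35.0% ± 10.8 untreated and 12.4% ± 7.4 at day 28 (adjusted p = 0.0847). The rise across it was 52.1 ± 11.5 points untreated and differed by -30.1 ± 13.9 points (SE) at day 28 (adjusted p = 0.112).

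**Figure D3:**
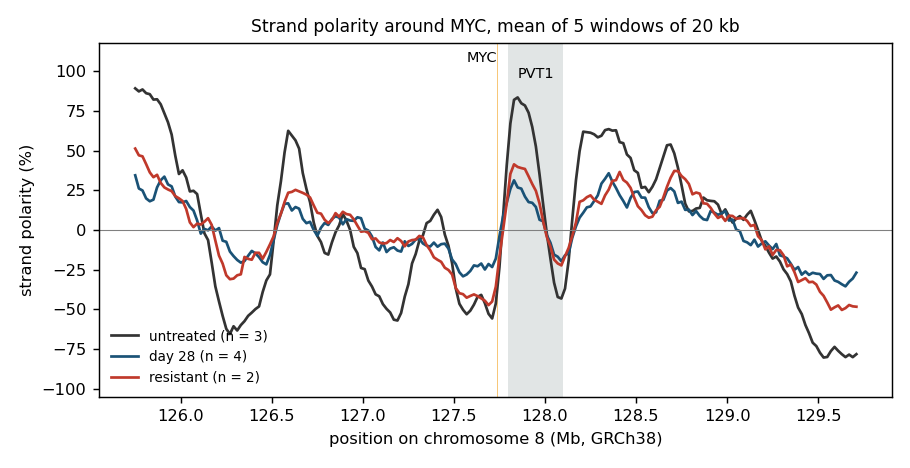
Strand polarity in percent along 4 Mb of chromosome 8 around MYC and PVT1 (shaded), as group means smoothed over 5 windows of 20 kb. All 3 curves turn from negative to positive between MYC and PVT1, and the untreated curve has the widest swings.

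Each called member of the fixed gene lists changed toward 0, that is against the sign of its untreated mean. Some, such as CCND1, ended beyond 0 on the other side. The counts below compare with 5710 of 17061 genes in mean polarity and 3003 of 12809 in the rise over all genes. Among EGFR and bypass oncogenes, 12 of 25 members tested changed in mean polarity (15 adjusted over the list alone), among them NRAS, BRAF, RET, FGFR2, YES1 and SRC. The list's median absolute polarity was 40.7% untreated and 15.6% at day 28. Across its genes, the slope of mean polarity at day 28 on the untreated mean was 29.4%, against 32.8% for all genes. This was the 15.7th percentile of 10000 random lists. ROS1, a receptor tyrosine kinase, went from -77.0% ± 4.1 to -22.2% ± 10.0 (adjusted p = 0.00953). Among cell cycle oncogenes 7 of 19 changed (11 adjusted over the list alone): MDM4, CDK6, MYC, CCND1, CCND2, MDM2 and AURKA. AURKA, a mitotic kinase, went from -87.3% ± 6.4 to -34.1% ± 5.9, while CCND1, which encodes cyclin D1, went from -19.9% ± 24.4 past 0 to 25.8% ± 9.7. Among tumour suppressors 8 of 17 changed (8 adjusted over the list alone), including APC, ATM, BRCA2 and SMAD4. The transcription factor SMAD4 went from 83.2% ± 6.5 to 24.3% ± 17.1. Among replication and licensing genes 9 of 21 changed in polarity (13 adjusted over the list alone) and 6 of 14 in the rise across them (8 adjusted over the list alone). TOP1, which encodes a DNA topoisomerase, changed in both, with a rise of 94.6 ± 9.9 points untreated and 21.9 ± 20.4 at day 28. CDC6, which loads the replicative helicase, lay between converging forks in untreated cells, with a rise of -89.8 ± 8.1 points, against 5.6 ± 21.6 at day 28 (adjusted p = 0.00126).

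Mesenchymal and persister genes changed in 9 of 22 members (9 adjusted over the list alone), among them TGFB2, CD44, SNAI2 and ITGB1. ITGB1, an integrin, went from -84.0% ± 5.9 to -19.4% ± 15.8. Epithelial lung genes changed in 2 of 13 (2 adjusted over the list alone), EPCAM and GRHL2. GRHL2, an epithelial transcription factor, went from 85.3% ± 5.6 to 31.0% ± 9.5. Long genes active in epithelial cells changed in 3 of 15 (2 adjusted over the list alone), PVT1, MYOF and SMAD3. Histone genes changed in 2 of 8 (2 adjusted over the list alone), H1-4 and H2BC5, which lie next to each other and share a window. Of 20 common fragile site genes, which are very long and replicate late, LSAMP alone changed in mean polarity (0 adjusted over the list alone; 2 at an unadjusted p under 0.05). The list's median absolute polarity was 9.95% untreated and 5.28% at day 28. These genes can span many windows (76 at FHIT and 96 at LRP1B), over which leftward and rightward stretches can cancel in the mean. Few calls in this measure therefore do not show that these genes were spared. FHIT and WWOX had polarities of 0.1% ± 6.0 and -9.2% ± 3.3 untreated and -4.6% ± 3.4 and -2.3% ± 6.6 at day 28, and neither passed the test. Polarity at MET was -2.4% ± 14.1 and 0.6% ± 16.2, and at CDKN2A 19.1% ± 21.1 and 11.3% ± 18.6, neither of them past the test. In the rise across genes, the called members were 6 of 19 EGFR and bypass oncogenes (6 adjusted over the list alone), 5 of 16 cell cycle oncogenes (6) and 1 of 13 tumour suppressors (1). They were also 2 of 9 fragile site genes (5), 2 of 14 epithelial genes (2), 0 of 11 mesenchymal genes (0), 0 of 10 long genes (0) and 2 of 8 histone genes (2). At an unadjusted p under 0.05 there were 2 mesenchymal and 4 long genes.

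Over all genes, 5710 of 17061 changed in mean polarity at day 28 (limma, adjusted p under 0.05), each of them toward 0, and 3003 of 12809 changed in the rise across them. Of the 20 kb windows, 9213 of 80351 changed (11.5%), each toward 0. These windows, picked for their change, had a median absolute polarity of 79.6% untreated and 15.6% at day 28. Over all 80351 windows the median in single libraries was 34.1% to 44.2% untreated and 17.2% to 25.0% at day 28. The largest increases named by the fixed rule were in KAZN (chromosome 1, 14940001 to 14960000), from -83.6% ± 18.6 to 39.0% ± 29.5, in PSD3 (chromosome 8, 18900001 to 18920000), in SSH2 (chromosome 17, 29840001 to 29860000) and 723364 bp from C4orf33 (chromosome 4, 129840001 to 129860000). The largest decreases were in MYO5B (chromosome 18, 49880001 to 49900000), which encodes a myosin motor, from 74.1% ± 5.11 to -44.9% ± 17.7, in GMDS (chromosome 6, 1780001 to 1800000), in DNAJC6 (chromosome 1, 65260001 to 65280000) and 129752 bp from FAM47A (chromosome X, 33980001 to 34000000). Scaled to the untreated amplitude with array weights, 7 windows of 20 kb and 51 of 100 kb were called; array weights without scaling gave 24976 windows of 20 kb and 4697 genes in the rise. A fit of the 2 groups alone gave 19560 windows, and the replicate number as a block 0. Calls of single windows hung on single libraries. Of the windows, 0 were left without any one of untreated replicates 1, 2 or 3 or without day 28 replicate 1, 2 without day 28 replicate 2, and 3694 without day 28 replicate 4. Leaving out day 14 replicate 1 or 2 gave 14312 and 14313. Without day 28 replicates 3 and 4 together 6067 were called. With all libraries, 9022 of 19312 windows were called at 100 kb, and that fit was not repeated without these 2. Gene counts moved less, with 2002, 1182 and 3708 genes changed in mean polarity without untreated replicate 1, untreated replicate 2 and day 28 replicate 2. There were 1363 and 1067 changed in the rise without untreated replicates 1 and 2.

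After 7 days, 1314 of 17061 genes had changed in mean polarity, 1306 of them toward 0, and 1093 of 12809 in the rise across them. The called list members in mean polarity were ROS1, HGF, CDK6, CCND1, APC, BRCA2, RRM2, POLE, ITGB1, H2BC11 and H2AC11, of which the last 2 share a window. ROS1 had gone to -30.4% ± 2.0 (SD, n = 2; adjusted p = 0.0341). CDK6, the kinase partner of cyclin D, went from 51.5% ± 4.7 to -0.5% ± 2.3 (adjusted p = 0.0392). HGF, the ligand of MET, went from 25.0% ± 15.9 to -26.2% ± 5.6 (adjusted p = 0.0437). The rise across CCNE1 had gone to 7.4 ± 21.9 points (adjusted p = 0.00601), that across TOP1 to 17.9 ± 10.3 points (adjusted p = 0.0252) and that across AXL to 47.7 ± 21.9 points (adjusted p = 0.0355). In the rise, ROS1, AXL, E2F3, CCNE1, SMAD4, TOP1, GRHL2, CCN2 and H3C2 were called. In mean polarity the lists counted 2 of 25 EGFR and bypass oncogenes (2 adjusted over the list alone), 2 of 19 cell cycle oncogenes (2), 2 of 17 tumour suppressors (5), 0 of 20 fragile site genes (0) and 2 of 21 replication genes (2). They also counted 0 of 13 epithelial genes (0), 1 of 22 mesenchymal genes (1), 0 of 15 long genes (0) and 2 of 8 histone genes (3). At an unadjusted p under 0.05 there were 0 fragile site, 2 epithelial and 5 long genes. EGFR, MET, ERBB2, MYC, CDKN2A, FHIT and WWOX did not pass the test in either measure, or lacked a value for the rise. The named windows with the largest increases lay in MLLT3, SPIDR and VWA8 and near STMN4, and those with the largest decreases in LRMDA and PTPRG and near CX3CR1 and SPACA1. In MLLT3 (chromosome 9, 20520001 to 20540000) polarity went from -89.3% ± 12.2 to 48.4% ± 7.77. In total 882 windows of 20 kb were called, and 4586 of 100 kb. With array weights the counts were 143 windows, 21 genes in mean polarity and 440 in the rise; without day 28 replicates 3 and 4 they were 262 windows and 583 genes in mean polarity. The windows were 523 with at least 1 value per group required, and 0 with day 28 replicates 3 and 4 placed at day 7, with the replicate number as a block or after scaling to the untreated amplitude with array weights (4779 at an unadjusted p under 0.05 in the scaled fit). The day 7 counts moved widely with single libraries. Windows numbered 0 without any one of the untreated replicates, 46 and 3108 without day 7 replicates 1 and 2, 3018 and 2998 without day 14 replicates 1 and 2. They numbered 1999, 390 and 203 without day 28 replicates 1, 2 and 3, and 267 and 269 without lines 5 and 10. Genes changed in mean polarity numbered 0, 0 and 3 without untreated replicates 1, 2 and 3, 0 without day 7 replicate 1, 2110 and 2099 without day 14 replicates 1 and 2, and 773 without day 28 replicate 2. Genes changed in the rise numbered 190, 156 and 648 without untreated replicates 1, 2 and 3 and 307 without day 7 replicate 1.

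After 14 days, 529 genes had changed in mean polarity, 522 of them toward 0, and 623 in the rise across them. Called list members in mean polarity were ROS1, TOP1, TOP2A, TWIST1 and ITGB1. TOP2A, the DNA topoisomerase of mitosis, had gone from -37.8% ± 7.9 to 22.9% ± 8.8 (SD, n = 2; adjusted p = 0.0498). TWIST1, a transcription factor of mesenchymal cells, went from 34.3% ± 12.8 to -35.7% ± 39.6 (adjusted p = 0.0441). In the rise, AKT1, E2F3, CDK4, CCNE1, CDC6 and PCNA were called. That across E2F3, a transcription factor of S-phase genes, had gone from 88.8 ± 17.4 to 18.7 ± 12.5 points (adjusted p = 0.0281). In mean polarity the lists counted 1 of 25 EGFR and bypass oncogenes (1 adjusted over the list alone), 0 of 19 cell cycle oncogenes (3), 0 of 17 tumour suppressors (3), 0 of 20 fragile site genes (0) and 2 of 21 replication genes (6). They also counted 0 of 13 epithelial genes (1), 2 of 22 mesenchymal genes (8), 0 of 15 long genes (0) and 0 of 8 histone genes (0). At an unadjusted p under 0.05 there were 7 cell cycle, 6 tumour suppressor, 0 fragile site, 3 epithelial, 2 long and 3 histone genes. None of EGFR, MET, ERBB2, MYC, CDKN2A, FHIT and WWOX passed the test in mean polarity or, where it had a value, in the rise. The named windows with the largest increases lay in FGD1 and RPRD1A and near TFAP2B and PAPOLA, and those with the largest decreases in PRKG1, APOO, TADA2A and PLEKHM1. In RPRD1A (chromosome 18, 36000001 to 36020000) polarity went from -89.0% ± 11.5 to 54.8% ± 16.8. In total 507 windows of 20 kb were called at day 14, and 2588 of 100 kb. With array weights the counts were 7 windows, 30 genes in mean polarity and 196 in the rise; without day 28 replicates 3 and 4 they were 176 windows and 133 genes in mean polarity. The windows were 964 with at least 1 value per group required, and 0 in a fit of the 2 groups alone, with the replicate number as a block or after scaling to the untreated amplitude with array weights (5038 at an unadjusted p under 0.05 in the scaled fit). These counts too moved with single libraries. Windows numbered 2, 0 and 12 without untreated replicates 1, 2 and 3, 1263 and 1262 without day 7 replicates 1 and 2, 871 and 2463 without day 14 replicates 1 and 2. They numbered 1157, 235 and 146 without day 28 replicates 1, 2 and 3, and 132 and 127 without lines 5 and 10. Genes changed in mean polarity numbered 13, 0 and 89 without untreated replicates 1, 2 and 3, 833 and 824 without day 7 replicates 1 and 2, and 254 and 861 without day 14 replicates 1 and 2. They numbered 153 and 177 without day 28 replicates 2 and 3, and 304 and 329 without lines 5 and 10. Genes changed in the rise numbered 48, 49 and 325 without untreated replicates 1, 2 and 3, 1019 and 1007 without day 7 replicates 1 and 2, and 273 without day 14 replicate 1.

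The resistant lines, which grow in osimertinib, had lower amplitudes than untreated cells and differed from each other. Line 5 had an amplitude of 0.285 and a rise of 24.6 points across initiation zones, within the ranges of the day 28 libraries (0.261 to 0.452 and 18.7 to 36.9 points), whereas line 10 had 0.641 and 57.2 points. Their windows with a value (93.0% and 93.1%) were alike. As a group they averaged 0.463 ± 0.252 (SD, n = 2), below each untreated library, with exact permutation p = 0.2, the smallest that 2 against 3 libraries allow; adjusted over the 6 comparisons it was 0.24. The difference from day 28 was smaller than the spread between the lines (exact permutation p = 0.4; the smallest possible is 0.133), and without line 10 its sign turned (-0.0445 in amplitude and -0.669 points in the rise). Mean polarity at EGFR was 7.6% ± 0.3 (SD, n = 2), at MYC -43.7% ± 22.4, and at ERBB2 24.9% ± 9.8. It was at MET -15.5% ± 13.3, at CDKN2A 12.7% ± 20.7, at FHIT -4.8% ± 4.6 and at WWOX -6.8% ± 1.4. No gene was called against untreated in mean polarity (4060 at an unadjusted p under 0.05) or in the rise (1911). Adjusted over the list alone, 4 of 21 replication genes, 3 of 17 tumour suppressors, 2 of 25 EGFR and bypass oncogenes and 2 of 8 histone genes passed in mean polarity, against 0 in each of the other lists, and 2 of 19 EGFR and bypass oncogenes, 2 of 16 cell cycle oncogenes and 3 of 14 replication genes in the rise. The 2 histone genes, H2BC11 and H2AC11, share a window and so are 1 measurement, which enters the adjustment over that list 2 times. No 20 kb window was called by limma (8664 at an unadjusted p under 0.05), but 1348 of 19312 were at 100 kb, 916 at 20 kb with array weights and 6324 in a fit of these 5 libraries alone. With array weights 1751 genes passed in mean polarity and 1396 in the rise. Without day 7 replicate 1 or 2, 1 gene passed in mean polarity. Against day 28 the counts were 0 windows (1191 at an unadjusted p under 0.05), 0 genes in mean polarity (280) and 0 in the rise (302). They were 0 with array weights as well, and at 100 kb for windows.

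Under osimertinib polarity fell less at long distances than at short ones, so that what remained reached further in relative terms. The covariance of polarity between windows 200 kb apart, relative to windows 20 kb apart, was 0.308 ± 0.0292 (SD, n = 3) untreated, 0.477 ± 0.0225 (SD, n = 2) at day 7, 0.536 ± 0.00703 (SD, n = 2) at day 14, 0.535 ± 0.0776 (SD, n = 4) at day 28 and 0.387 ± 0.0157 (SD, n = 2) in the resistant lines. Over the 8 osimertinib libraries it was 0.521 ± 0.0583 (SD, n = 8) and differed from untreated with p = 0.0121 by two-sided exact permutation, the smallest possible. The resistant lines lay above each untreated library and below each osimertinib library (exact permutation p = 0.2 against untreated and 0.133 against day 28, the smallest possible in both cases). This measure was chosen after the data were seen.

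**Figure D4:**
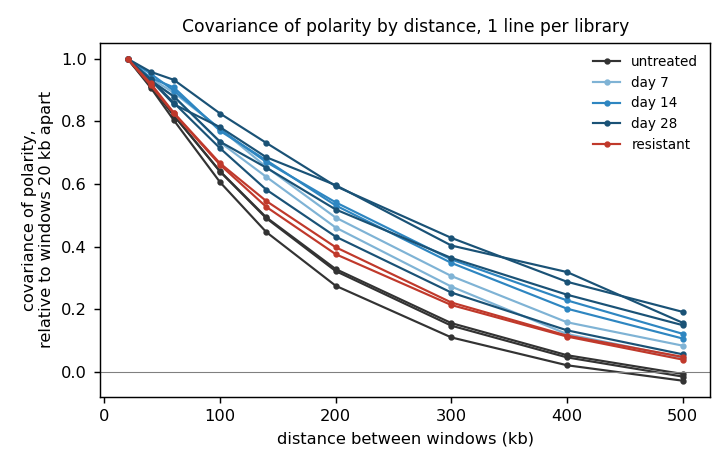
Covariance of strand polarity between windows, relative to windows 20 kb apart, against the distance between them in kb, with 1 line per library. At 200 kb the untreated libraries lie between 0.275 and 0.328, both resistant lines between 0.376 and 0.398, and the osimertinib libraries between 0.432 and 0.596.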

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

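The test of the mitochondrial genome was chosen after its values were seen. The mitochondrial genome was outside all comparisons of nuclear windows, and its polarity was more negative under osimertinib: the window from 1 to 16569 had a polarity of -67.1% ± 8.32 (SD, n = 8) in osimertinib libraries and -47.2% ± 10.0 (SD, n = 3) in untreated ones. The two-sided exact permutation p was 0.0242, and 0.170 after adjustment over the 7 windows of the mitochondrial genome and the ribosomal repeat, so the difference did not pass the correction. The lowest untreated value, -58.6%, lay within the osimertinib range of -79.0% to -58.2%. Lines 5 and 10 had -46.9% and -74.0%. No explanation was tested. In the 4 day 28 libraries no value passed Dixon's test for an outlier in amplitude, zone rise, ratio of slopes, share of windows with a value or mean correlation with the untreated libraries. In the last of these, day 28 replicate 3 was highest at 0.792, against 0.342, 0.496 and 0.471 in replicates 1, 2 and 4, and its gap of 0.659 of the range lay under the critical value.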

How the results depend on the processing

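Alternatives on values scaled to the untreated amplitude, array weights for genes, every alternative for gene counts, treated libraries alone for the time course, and other slopes, offsets and chromosome sets were added after the data were seen. The lower amplitude and zone rise of osimertinib against untreated kept direction and an unadjusted exact permutation p under 0.05 in each alternative run. The adjusted p of the main run was 0.0727 for both. When each library was left out in turn, amplitude differences were -0.619 to -0.467 and zone differences -62.5 to -51.4 points. Placing day 28 replicates 3 and 4 at day 7 leaves this pooled group unchanged, so that alternative could not alter it. For resistant minus day 28 the amplitude difference ran from -0.0445 to 0.312 and the zone difference from -0.669 to 32.0 points, the negative values being those without line 10. The relation of amplitude to day, past the threshold over untreated and treated libraries together, was not within the treated ones alone (r = -0.50). Counts of windows moved most, for day 7, day 14, day 28 and resistant against untreated in that order: at 100 kb 4586, 2588, 9022 and 1348; with array weights 143, 7, 24976 and 916; scaled to the untreated amplitude with array weights 0, 0, 7 and 0, and at 100 kb 2, 4, 51 and 362. With only the 2 groups compared, day 14 gave 0, day 28 19560 and resistant 6324. Without day 28 replicates 3 and 4 the first 3 counts were 262, 176 and 6067, and with these placed at day 7, day 7 gave 0. With windows that had at least 1 value in every group, day 7 gave 523 and day 14 964. With the replicate number as a block, days 7, 14 and 28 gave 0, 0 and 0. Same-numbered libraries deviated together at r of only -0.0739 to 0.0691 across windows, against -0.111 to 0.111 for other numbers. The numbers were therefore not taken to pair the libraries. In groups of 2 libraries the deviations mirror each other, so this check is weak. For amplitude and zone rise only the differences within numbers 1 and 2 were taken, which allows no test. Gene counts were not fitted with a block. Leaving out each library in turn gave 0 to 3108 windows at day 7, 0 to 2463 at day 14 and 0 to 14313 at day 28. Genes changed in mean polarity numbered 0 to 2110, 0 to 861, 1182 to 6358 and, for resistant, 0 to 1, and those changed in the rise 156 to 1498, 48 to 1019 and 1067 to 3498; where 1 library of a group was left, it was assumed to vary like the others. Without day 28 replicates 3 and 4, genes changed in mean polarity were 583 at day 7 and 133 at day 14. With array weights they were 21, 30 and 1751 at day 7, day 14 and in the resistant lines, and for the rise 440, 196, 4697 and 1396 at day 7, 14, 28 and in the resistant lines. The cause of these moves was not tested. Not run, for want of counts, were all alternatives of read density and of chromosome shares, the priors and minimums of reads, equal depths and the correction for counting variance. Depth itself is unknown.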

Other observations

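The tests in this part were chosen after the results were seen, except that of one smoothing shared by day 28 and the resistant lines. Some regions differed in polarity after each library's amplitude was matched to the untreated ones, at 100 kb but hardly at 20 kb. When each library was scaled to the untreated amplitude and 100 kb windows were tested with array weights in limma, 362 of 19312 windows differed between the resistant lines and untreated cells, of which 199 had changed sign, and 51 differed at day 28, of which 33 had changed sign. Counts were 2 at day 7, 4 at day 14 and 0 between the resistant lines and day 28 (981 at an unadjusted p under 0.05). At 20 kb the same limma fit called 0 windows in the resistant lines (6375 at an unadjusted p under 0.05) and 7 at day 28. The largest changes in the resistant lines lay at LAMA4, a laminin chain (chromosome 6, 112200001 to 112300000; from 2.94% ± 16.9 to 105% ± 21.6 on the scaled axis, which can exceed the limit of raw polarity), and in SLC14A2, a urea transporter (chromosome 18, 45400001 to 45500000; from -45.0% ± 14.5 to 52.9% ± 40.7). Others lay at EFNB2, an ephrin ligand (chromosome 13, 106500001 to 106600000; from 66.4% ± 27.6 to -25.1% ± 20.5), at MSRB3 (chromosome 12, 65400001 to 65500000; from -31.7% ± 21.9 to 58.6% ± 5.88) and in THRB, a thyroid hormone receptor (chromosome 3, 24300001 to 24400000; from -6.61% ± 6.31 to 91.0% ± 19.3). The window at EFNB2 (-15.5% ± 52.9 at day 28) and one 115492 bp from NLRP1 (chromosome 17, 5700001 to 5800000; -32.9% ± 12.2 untreated, 44.0% ± 36.7 at day 28 and 53.6% ± 29.1 in the resistant lines) were called in both comparisons. At day 28 the largest changes in the weighted fit lay at RASSF2 (chromosome 20, 4700001 to 4800000; from 21.1% ± 22.6 to -61.3% ± 41.9) and 410996 bp from SPDYE21 (chromosome 7, 67700001 to 67800000; from -4.04% ± 8.90 to 108% ± 29.3). Both rankings use the weighted estimates of the fit, whereas the means printed are unweighted. By unweighted means some windows changed more at day 28 than that at RASSF2, such as the one at HERC1 (from 33.2% ± 14.2 to -65.7% ± 49.3). These genes were named after their values were seen.

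Of the 51 windows called at day 28, 23 were also called in the resistant lines, and 23 of these 23 changed in the same direction, against 0.280 and 0.198 windows expected of independent lists in each direction. Both comparisons share the untreated libraries, so some overlap is built in, and its size was not simulated. For the correlation across windows, which are not independent replicates, unchanged groups simulated against these libraries gave 0.0982, against 0.381 observed. Against a different untreated library on each side, the mean correlation was 0.280 (0.200 to 0.331 over 6 pairings), and putting the third untreated library in place of the resistant lines gave at most 0.0744, which argues against noise of the shared libraries as the whole source. A common smoothing of the untreated profile is argued against by a mean correlation of 0.242 (0.160 to 0.306) after the third untreated library at 10 windows on either side was regressed out of both changes. Whether a shared shift in which initiation zones are used underlies this was not tested. A link to changes in transcription was not tested either, as no expression data were used here.

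The loss of amplitude under osimertinib has several candidate sources. The loss was also seen at like coverage. Of the osimertinib libraries, 2 had at least as many windows with a value as the least covered untreated library. The higher of their amplitudes was 0.452, below the lowest untreated one (0.807). It belonged to day 28 replicate 3, whose labels conflict. Counting noise in the tested library does not by itself shift such a slope, so this comparison says little on fewer reads as a cause. Reads without strand preference added to each window in proportion would lower all scales alike. However, the slope at 500 kb divided by that at 20 kb averaged 1.17 over the 8 osimertinib libraries and 1.00 in untreated ones. Reads added in this proportion therefore cannot be the whole cause, while reads without strand preference spread otherwise could not be checked without counts. Such reads may still account for most of the loss, since a culture with fewer cells in S phase yields fewer fork ends; their share cannot be had without counts. The series' design text says that the 28-day cultures did not proliferate, and whether fewer replicating cells, weaker zones or a wider choice of initiation sites per cell lie behind the loss was not tested.

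The longer relative reach of polarity under osimertinib was also seen at like coverage. The ratio of slopes at 500 kb and 20 kb in the 2 well covered osimertinib libraries was at least 1.11, against at most 1.003 in untreated ones. The value of 1.11 is that of day 28 replicate 3, whose labels conflict. As both slopes are not shifted by counting noise in the tested library, this too says little on fewer reads. Loss of initiation zones that lie close together would spare isolated zones: the share of the untreated rise kept at zones 800 to 1600 kb from the next, divided by that at zones 200 to 400 kb from it, averaged 1.13 over the osimertinib libraries with a range of 1.02 to 1.39, and this spread leaves it open. Other spacings showed no steady trend: at day 28 the shares kept, from the closest zones (under 200 kb) to the most isolated (over 1600 kb, under 20 zones), were 27.8% ± 8.91, 28.1% ± 10.8, 29.6% ± 10.2, 32.4% ± 9.35 and 27.9% ± 10.7 (SD, n = 4). The rise per unit of amplitude was 76.6 ± 5.01 (SD, n = 8) under osimertinib, 87.8 ± 2.05 (SD, n = 2) in the resistant lines and 93.8 ± 2.58 (SD, n = 3) untreated (osimertinib against untreated, exact permutation p = 0.0121, the smallest possible).

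Of the 35 splits of the 7 untreated and day 28 libraries, 1 called as many windows as the real one (19560 in a fit of these groups alone, highest other 7368). Likewise 1 called as many genes in mean polarity (6938, highest other 2750) and 1 as many genes in the rise (4023, highest other 2101). The real split thus ranked first in each count. That is the strongest outcome 35 splits allow, and it does not exclude chance. In each case the highest other split set day 28 replicates 1, 2 and 4 against the untreated libraries and day 28 replicate 3.

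For each list, the slope of a group's mean polarity on the untreated mean was taken across the list's genes, in percent. Such a slope is not the share of polarity kept at each gene. In this slope, 5 of 27 list and group pairs lay below the 5th or above the 95th percentile of 10000 random lists with matched numbers of windows. By chance 2.7 are expected, and the pairs share libraries and are not independent. No list did so in every group. Common fragile site genes had slopes of 52.6% under osimertinib (94.6th percentile) and 56.9% in the resistant lines (96.4th percentile), against 41.2% and 47.7% for all genes. Histone genes had slopes of 53.8% at day 28 (96.1st percentile) and 27.4% in the resistant lines (4.86th percentile), where some of the 8 members share windows. Their median absolute polarity was 47.0% untreated, 16.4% at day 28 and 11.3% in the resistant lines, so the high slope at day 28 does not show that they were spared. In the resistant lines, replication and licensing genes had a slope of 38.7% (4.55th percentile) and cell cycle oncogenes one of 55.9%, just above the 95th percentile. In the ribosomal repeat, polarity was -35.7% ± 42.7 (SD, n = 3) from 1 to 20000 and 59.3% ± 13.1 (SD, n = 3) from 30001 to 42999 in untreated libraries, and -33.6% ± 25.5 and 38.0% ± 19.9 (SD, n = 8) under osimertinib; the differences had exact permutation p-values of 0.945 and 0.133.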
